A study of Homo sapiens with 16 samples.

How the data were processed

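Ribosome-protected fragments (RPF) and total RNA were measured in MDA-MB-231 cells with CRISPRi against eGFP or against tRNA-Ile-GAU and with a control construct or a construct for tRNA-Ile-UAU. Per the labels, cells grew in DMEM with serum, were lysed with cycloheximide, and ribosomes were pelleted through sucrose before RNA was extracted with Trizol. Samples were grouped by assay, CRISPRi target and construct as their titles give them, 2 libraries per group and 8 groups. The libraries of a group carry numbers, which the labels do not pair across groups. Correlations of the deviations from the group means between libraries of the same number were -0.04 to 0.06 in RPF. In total RNA they ran from -0.42 (construct with double modulation) to 0.36 (knockdown with double modulation). With both signs, the values give no pairing that holds across groups, though these RNA groups shared part of the difference between their replicates.

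The deposited values are raw read counts per gene symbol. Per the submitters' processing notes, the authors used cutadapt 1.17, STAR 2.5.2a and HTSeq with build hg38; the order, the settings, the annotation and the HTSeq version are not stated. The total RNA files list 26485 genes each, 0 counts included. The RPF files list genes with at least 1 read, 13804 genes in any of them and 9852 in all, and a gene missing from a file was given a count of 0. The 5 HTSeq summary lines of each file were left out of the tests and used for depth. Alignments to several places made up 97.0 to 98.8% of all that HTSeq saw in RPF and 97.2 to 98.1% in total RNA. Reads counted on genes made up 0.843 to 2.25% and 0.690 to 1.00%. Of uniquely placed reads, 24.8 to 32.6% in RPF and 62.2 to 65.0% in total RNA fell on no gene, and 0.265 to 0.296% and 1.07 to 1.63% on several genes. Chromosomes and positions came from tables of GRCh38.p14. There, 23925 of the symbols are current names, 1459 were matched as older names, and 1101 are in neither table and have no position here.

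Depth and precision were as follows. Counts on genes were 358340 to 938909 per RPF library and 2512247 to 5446599 per total RNA library, on 10974 to 11984 and 14969 to 16129 genes with a count. The most abundant gene took 1.14 to 1.39% of the counts in RPF (VIM) and 0.642 to 1.08% in total RNA (MALAT1). The biological coefficient of variation from edgeR was 6.71% in RPF, 14.3% in total RNA and 12.5% over both. Replicates correlated at 0.947 to 0.970 in RPF and 0.958 to 0.986 in total RNA (log2 CPM, across genes). The tests were tested on simulated data. In counts simulated at these depths and spreads, with 100 genes changed 1.5-fold and 100 changed 2-fold in the double modulation, the tests called 26 of the 98 tested 1.5-fold and 64 of the 99 tested 2-fold changes in RPF. They called 4 of 100 and 36 of 100 in total RNA and 1 of 98 and 14 of 99 in translational efficiency. No call had the wrong sign, and 3, 3 and 1 unchanged genes were called. The counts of each gene were drawn independently, so shifts shared by many genes of a library were not simulated.

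Genes were tested with edgeR 4.0.16 in R 4.3.3. Within each assay, genes were kept by filterByExpr (minimum count 10, minimum total 15, by group), libraries were scaled by TMM, and edgeR's quasi-likelihood test was run on all 8 libraries with group means and 4 residual degrees of freedom. The comparisons made were the double modulation, tRNA-Ile-UAU overexpression and tRNA-Ile-GAU knockdown, each against control, and their interaction, the effect of the construct in knockdown cells minus that in eGFP cells. Translational efficiency was the difference of the RPF and total RNA contrasts in 1 fit of all 16 libraries (8 residual degrees of freedom), on genes kept in both assays. P-values were adjusted by Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. Log2 CPM values used a prior count of 2, and the errors beside log2 fold changes are standard errors from the model, those beside CPM standard deviations.

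Gene lists were written from general knowledge before the data were examined, as were the groups, the tests, the comparisons, the rule for named genes and the alternatives, other than those said to be added. The 29 lists cover cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, tRNA processing with polymerase III, splicing, the proteasome, heat shock, unfolded protein and integrated stress responses, cholesterol synthesis, glycolysis, hypoxia, and nuclear and mitochondrially encoded respiratory genes. They also cover replication, histones, mitosis, p53, immediate early, NF-kB, interferon and YAP targets, extracellular matrix, nuclear noncoding RNAs, and luminal, fibroblast, immune and endothelial markers. Symbols matched in full, other than 22 of 23 synthetases, 17 of 18 histones and 0 of 13 mitochondrially encoded genes. Lists with at least 5 tested members were tested by camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with the correlation estimated from the data beside it. Members were also adjusted over the list alone.

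The genes named in the text were chosen by rule. In each layer these are the 10 genes per direction with the largest log2 fold change in the double modulation, 5 per direction for each single change, among genes with adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups' values. For the interaction they are the 3 per direction with the lowest p among those that passed, and where none passed, the 3 with the lowest p. Up to 4 members with the lowest p were named per list, and IARS and IARS2 in any case. PDGFC, TGM2 and HTR1F lie outside the rule and were named, because few genes passed there, after their values were seen; so were the genes named only for lying on chromosome 7 or for passing in both backgrounds.

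Alternatives tried were size factors (RLE) in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom for translational efficiency, a replicate block, a block that joins the assays of a culture, fits with only the groups compared, both assays in 1 fit, camera with the estimated correlation, agreement over genes above the median count, and leaving out each library in turn. Added after the data were seen were limma-voom with sample quality weights, the ribosomal protein score of each total RNA library as a covariate, lists without each library in turn, fits without chromosome 7 genes, and footprint libraries thinned to the total of the shallowest. Tests on chromosomes were also added after the data were seen, with camera over 23 chromosomes and medians in windows of 20 Mb. So were comparisons of chromosome medians and list scores per library between 4 and 4 libraries by exact permutation (70 arrangements), and fits of 4 against 4 libraries with their other splits. Figures and summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The planned tests of isoleucine codon content need coding sequences, which were not used here.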

Results

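Ribosome-protected fragments (RPF, the pieces of mRNA that a ribosome shields from nuclease, called footprints here) and total RNA were sequenced from MDA-MB-231, a human triple-negative breast cancer cell line. The cells carried CRISPR interference (CRISPRi, in which a guide RNA brings a repressor to a gene) against eGFP, the control target, or against tRNA-Ile-GAU. They also carried either a control construct or a construct that overexpresses tRNA-Ile-UAU. These 4 conditions were measured by both assays, which gave 8 groups of 2 libraries and 16 libraries in all. By its design text, the series asks how ribosomes occupy transcripts rich in isoleucine codons when tRNA-Ile-UAU is raised and tRNA-Ile-GAU is lowered. An anticodon UAU reads the isoleucine codon AUA, and an anticodon GAU reads AUC and AUU. Codon content was not analysed here. The footprint libraries held 358340 to 938909 counts on genes and the total RNA libraries 2512247 to 5446599. The 4 footprint libraries with the eGFP guide (358340 to 607919 counts) were shallower than the 4 with the tRNA-Ile-GAU guide (639320 to 938909). The labels number the replicates but do not say that they are separate cultures, so p-values measure only the spread between these samples, which may be technical.

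The targets themselves come first. Of the 26485 genes listed in each total RNA file, 0 were named as a tRNA-Ile gene, so the levels of tRNA-Ile-GAU and tRNA-Ile-UAU, and with them the labels, were not analysed here. The 3 tRNA-Ile-GAU genes lie on chromosome X of GRCh38.p14, at 3838377 to 3838450, 3876801 to 3876874 and 3915230 to 3915303. PRKX, a protein kinase gene at 3604340 to 3713649, was the tested gene within 1 Mb of them. Its total RNA differed by a log2 fold change of 0.13 ± 0.26 (SE, n = 2 per group) in the knockdown alone (adjusted p = 0.998). IARS and IARS2, the cytosolic and mitochondrial isoleucyl-tRNA synthetases, passed in no comparison. In the double modulation, IARS footprints differed by 0.13 ± 0.12 (adjusted p = 0.746) and IARS2 footprints by -0.04 ± 0.16 (adjusted p = 0.957). IARS2 total RNA differed by -0.35 ± 0.11 there (adjusted p = 0.365), and it passed when replicate 2 of the double modulation was left out, at -0.47, and with the ribosomal protein score of each library as a covariate, at -0.32.

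With knockdown of tRNA-Ile-GAU alone, against the eGFP guide with the control construct, footprints of 37 genes rose and those of 53 fell, of 8143 tested. The arms are named by their labels. The guide, the tRNA and the cells that received the guide coincide in the design. A difference between the arms, here and below, can therefore not be ascribed to any 1 of them. CDH11, a cadherin of mesenchymal cells, rose 4.72-fold, from 20.3 ± 0.10 to 96.4 ± 13.5 CPM (counts scaled to the same library total; SD, n = 2). Its log2 fold change was 2.24 ± 0.28 (adjusted p = 3.23e-10). S100A4, a calcium-binding protein linked to metastasis, was 2.39-fold lower, at 343 ± 44.2 against 820.4 ± 19.6 CPM (log2 -1.26 ± 0.12, adjusted p = 1.97e-16). The orphan receptor GPRC5C went from 98.9 ± 1.68 to 34.0 ± 3.05 CPM (log2 -1.53 ± 0.24, adjusted p = 1.27e-06). ZNF10, a KRAB zinc finger repressor, rose from 173 ± 17.1 to 502 ± 17.6 CPM (log2 1.53 ± 0.14, adjusted p = 1.71e-16). PTK7, a receptor pseudokinase of Wnt and cell polarity signalling, rose from 35.5 ± 0.176 to 89.8 ± 7.58 CPM (log2 1.34 ± 0.25, adjusted p = 0.000122). IGFBP1, which binds insulin-like growth factors, fell from 109 ± 10.2 to 44.9 ± 8.08 CPM (log2 -1.28 ± 0.22, adjusted p = 2.27e-05). LXN, the carboxypeptidase inhibitor latexin, and the hair keratin KRT85 also rose (log2 1.89 ± 0.54 and 1.65 ± 0.44, adjusted p = 0.0496 and 0.0309). The paraoxonase PON2 fell (log2 -2.43 ± 0.58, adjusted p = 0.00937). On GRCh38.p14, CDH11 lies on chromosome 16 (64943753 to 65123744), S100A4 on chromosome 1 (153543621 to 153545806), GPRC5C on chromosome 17 (74432088 to 74451658) and ZNF10 on chromosome 12 (133130627 to 133159465). PTK7 lies on chromosome 6 (43076314 to 43161715) and IGFBP1 on chromosome 7 (45888488 to 45893660). The count of 90 genes was 30 and 18 without control replicates 1 and 2, 32 and 46 without knockdown replicates 1 and 2, and 25 by DESeq2, which gave no adjusted p for 8 of the 10 named genes. It was 59 with the footprint libraries thinned to the shallowest, where PTK7 (adjusted p = 0.0522) and LXN (0.123) did not pass and PON2 fell under the filter on low counts. Of these genes, LXN, KRT85 and PON2 lost the call without control replicate 1 (highest adjusted p = 0.574), control replicate 2 (0.502), knockdown replicate 1 (0.297) or knockdown replicate 2 (0.175).

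**Figure D1:**
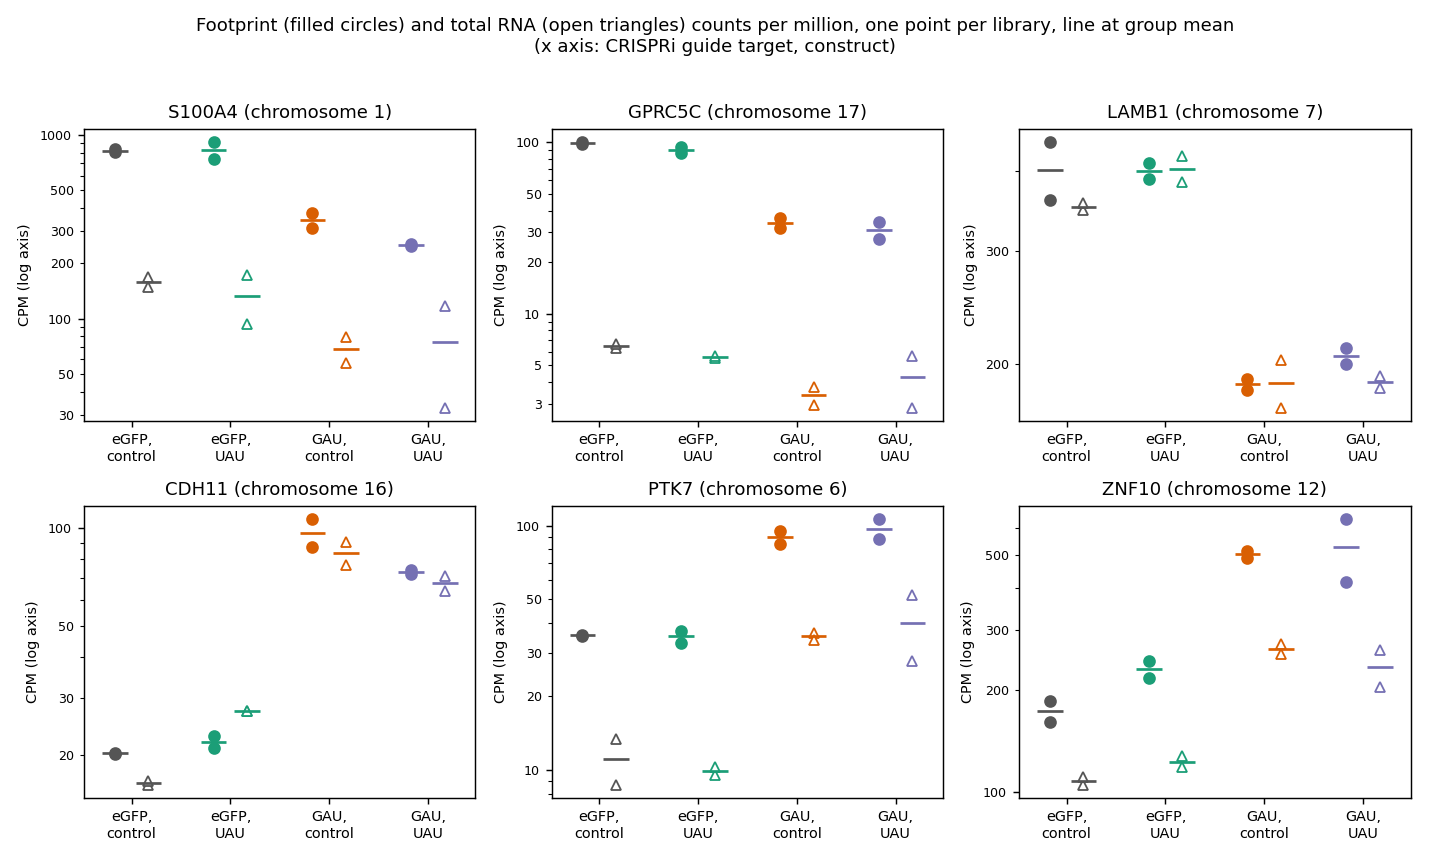
CPM on a log axis for 6 genes in the 4 conditions, with filled circles for footprint libraries, open triangles for total RNA libraries and a line at each group mean of 2 libraries. S100A4, GPRC5C and LAMB1 footprints lie lower in all 4 libraries with the tRNA-Ile-GAU guide and CDH11, PTK7 and ZNF10 footprints higher; S100A4 goes from 820.4 CPM in the control to 343 in the knockdown.

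The genes that fell were concentrated on chromosome 7, a pattern looked for only after the fallen genes had been seen. That chromosome held 32 of the 53 fallen genes against 2.41 by chance, 371 of the 8143 tested genes (4.56%) and 0 of the 37 risen genes. Among the fallen were LAMB1 (laminin beta 1, log2 -1.11 ± 0.14, adjusted p = 3.23e-10), HSPB1 (heat shock protein 27, -0.82 ± 0.14, adjusted p = 1.33e-05) and the tight junction gene CLDN4 (-0.85 ± 0.19, adjusted p = 0.00353). The median log2 fold change of the chromosome's genes was -0.39 in footprints, with 326 of 371 lower, and -0.39 in total RNA, with 514 of 553 lower. Medians of the other chromosomes lay between -0.08 (chromosome 19) and 0.13 (chromosome 13) in footprints and between -0.04 and 0.09 in total RNA. In 8 windows of 20 Mb along chromosome 7 the medians ran from -0.46 to -0.29 in footprints and from -0.49 to -0.31 in total RNA. With the construct alone the chromosome's median was -0.01 in footprints and -0.02 in total RNA. Per library, the 4 footprint libraries with the tRNA-Ile-GAU guide had a median of -0.17 ± 0.01 relative to the mean of all 8 and the 4 with the eGFP guide one of 0.19 ± 0.01 (SD, n = 4). The exact two-sided permutation p was 0.0286, the smallest that 70 arrangements allow, and 0.438 after adjustment over 92 tests. That smallest p could pass the adjustment only if most of the 92 tests reached it, so the adjusted value cannot decide. As a gene set among 23 chromosomes it was lower in footprints (camera adjusted p = 2.02e-33; adjusted p = 0.000285 with an estimated correlation) and in total RNA (7.87e-55; adjusted p = 6.06e-05 with an estimated correlation). With chromosome 7 genes left out of the fit, 26 genes rose and 16 fell, and LXN (adjusted p = 0.0832) and KRT85 (0.0508) no longer passed.

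**Figure D2:**
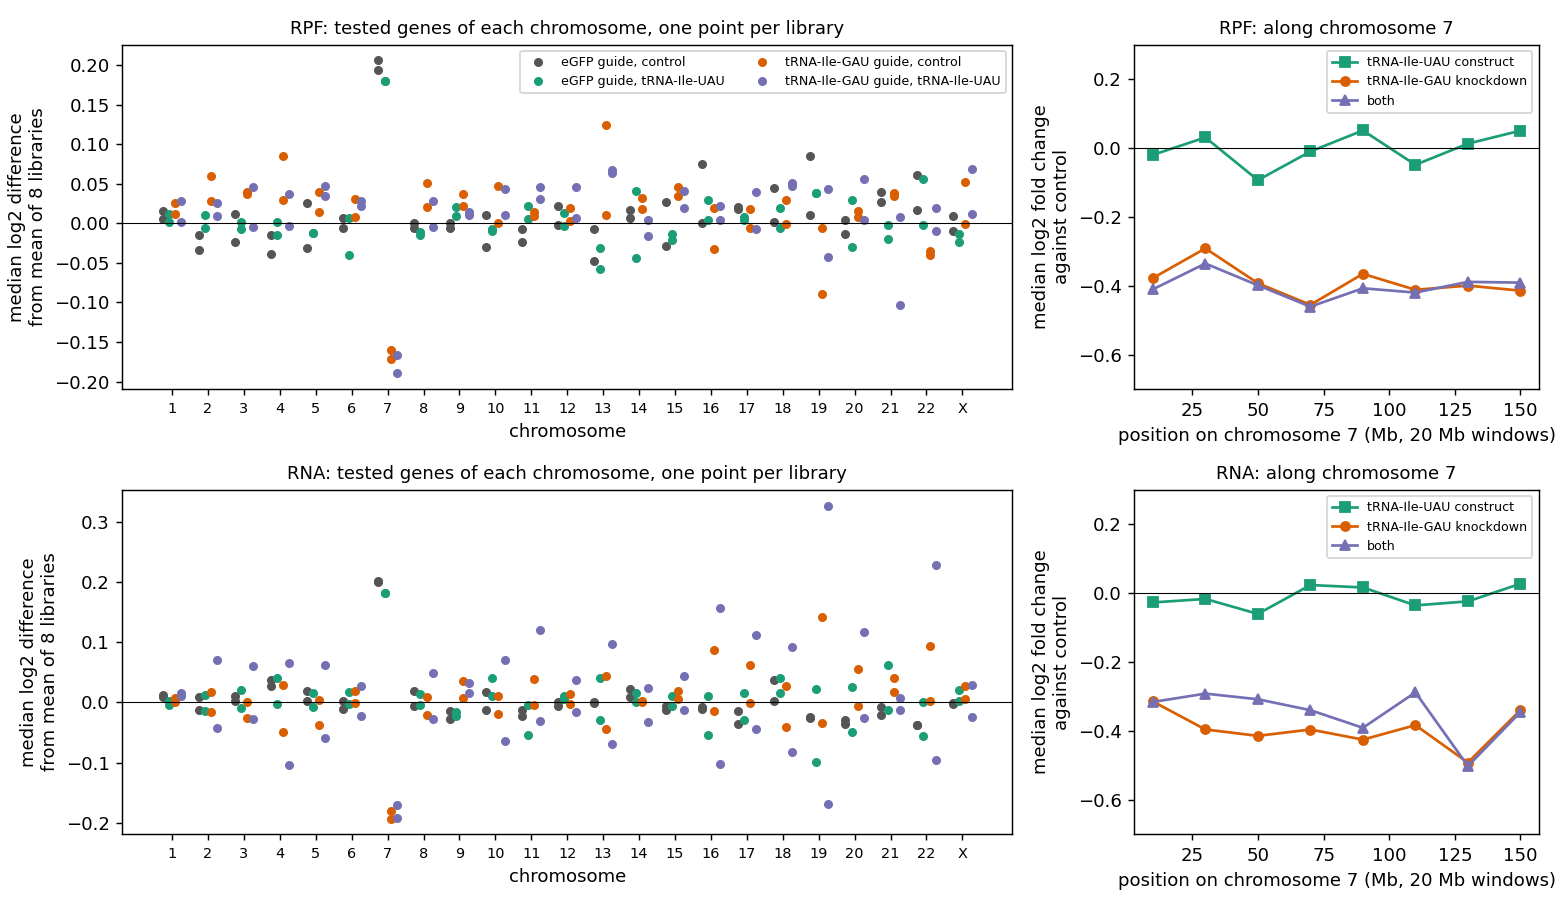
The panels on the left show, per library and chromosome, the median over tested genes of log2 CPM minus the mean of the 8 libraries of that assay (1 point per library, coloured by condition); the panels on the right show median log2 fold changes against control in windows of 20 Mb along chromosome 7. On chromosome 7 the libraries with the tRNA-Ile-GAU guide lie at -0.17 on average in footprints and the others at 0.19.

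Among the lists, the 50 tested ribosomal protein genes had lower footprints in the knockdown alone. Their median was -0.15 with 40 of 50 lower, and 2 fell over all genes (RPS15, -0.53 ± 0.13, and RPS16, -0.47 ± 0.12) and 7 when adjusted over the list alone (camera adjusted p = 2.33e-05; adjusted p = 0.999 with an estimated correlation). Of the 25 extracellular matrix genes, 4 fell over all genes, among them LAMB1 on chromosome 7, LAMA5 (laminin alpha 5, -0.57 ± 0.12) on chromosome 20 and TGFBI (-0.46 ± 0.12) on chromosome 5. Adjusted over the list alone, 5 fell and 1 rose. The list's median was -0.05 (camera adjusted p = 0.00216; adjusted p = 0.999 with an estimated correlation). It no longer passed without chromosome 7 genes (adjusted p = 0.178), without control replicate 2 (0.215) or without knockdown replicate 2 (0.847). Members of lists that did not pass also changed. SLC7A5 and SLC3A2, the subunits of a transporter of large neutral amino acids such as isoleucine, fell (-0.44 ± 0.12 and -0.39 ± 0.11, adjusted p = 0.0436 and 0.0464), and they are the 2 of 17 integrated stress genes that passed. TARS, the threonyl-tRNA synthetase, rose (0.44 ± 0.11, adjusted p = 0.0203), 1 of 22 synthetase genes, 1 also when adjusted over the list alone. CYR61 and CTGF, secreted targets of YAP, fell (-0.65 ± 0.11 and -0.47 ± 0.12) among 15 YAP targets, where 4 fell and 1 rose when adjusted over the list alone. Ribosomal protein and histone genes share sequence with near-identical copies and pseudogenes, and reads that align to several places were not counted, so their levels are uncertain throughout.

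The double modulation, knockdown of tRNA-Ile-GAU together with the tRNA-Ile-UAU construct, is the change named in the design text. Against control it raised the footprints of 43 genes and lowered those of 114, of 8143 tested. S100A4 was 3.25-fold lower, at 252 ± 5.76 against 820.4 ± 19.6 CPM (log2 -1.70 ± 0.13, adjusted p = 9.77e-25) and GPRC5C 3.14-fold lower (log2 -1.65 ± 0.24, adjusted p = 3.98e-07). The Wnt5a receptor ROR2 was 4.22-fold lower, at 13.9 ± 7.50 against 54.9 ± 17.7 CPM (log2 -2.08 ± 0.36, adjusted p = 3.4e-05). CDH11 rose 3.58-fold to 72.9 ± 1.38 CPM (log2 1.84 ± 0.30, adjusted p = 3.29e-06). ZNF10 rose 2.99-fold to 526 ± 155 CPM (log2 1.58 ± 0.15, adjusted p = 1.55e-17) and PTK7 2.76-fold to 96.9 ± 12.8 CPM (log2 1.47 ± 0.24, adjusted p = 8.67e-06). LXN rose from 5.92 ± 3.61 to 25.6 ± 4.62 CPM (log2 2.11 ± 0.52, adjusted p = 0.00978). EXOSC3, a subunit of the RNA exosome, rose by 1.29 ± 0.27 (adjusted p = 0.00106). PPAT, the enzyme of the committed step of purine synthesis, rose from 24.5 ± 3.46 to 55.5 ± 16.4 CPM (log2 1.12 ± 0.31, adjusted p = 0.0267). The remaining risen genes named by the rule were IFT172, DIAPH2, CLDN7 and SETD5, with log2 fold changes from 0.96 to 1.44. Other fallen ones were HHIPL1, PON2, VSTM2L, MDK (the growth factor midkine), the hexose transporter gene SLC2A6 and CRIP2, with log2 fold changes from -3.11 to -1.51. Of the fallen genes, 44 lie on chromosome 7 against 5.19 by chance, and 0 of the risen; the median of that chromosome's genes was -0.40 in footprints. Without chromosome 7 genes in the fit, 31 rose and 67 fell, and DIAPH2, CLDN7 and SETD5 no longer passed. The count of 157 genes was 57 and 35 without control replicates 1 and 2, 133 and 98 without double modulation replicates 1 and 2, and 48 by DESeq2, which gave no adjusted p for 18 of the 20 named genes. It was 82 with the footprint libraries thinned to the shallowest. There LXN, EXOSC3, PPAT, DIAPH2, CLDN7, SETD5, MDK and CRIP2 did not pass (highest adjusted p = 0.758), and HHIPL1, PON2 and VSTM2L fell under the filter on low counts. CDH11, ZNF10, PTK7, S100A4 and GPRC5C passed without any 1 library. Of the 20 named genes, 10 lost the call without control replicate 1 (highest adjusted p = 0.343), 13 without control replicate 2 (0.653), 12 without double modulation replicate 1 (0.526) and 8 without its replicate 2 (0.352).

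Among the fixed lists, cholesterol synthesis genes and histones had lower footprints in the double modulation. Of 21 cholesterol genes 3 fell (6 when adjusted over the list alone). Among them were INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum (-0.81 ± 0.16, on chromosome 7), and DHCR7, the last enzyme of the pathway (-0.57 ± 0.14). The median was -0.33 with 19 of 21 lower (camera adjusted p = 1.17e-07; adjusted p = 0.386 with an estimated correlation). Of 16 histone genes 6 fell (10 when adjusted over the list alone), among them HIST1H4C (-0.54 ± 0.11), HIST1H1E (-0.45 ± 0.10) and H3F3B (-0.62 ± 0.15), which encodes the replication-independent variant H3.3. Their median was -0.35 (camera adjusted p = 6.95e-09; adjusted p = 0.386 with an estimated correlation). Of 29 translation factors 3 rose (6 when adjusted over the list alone): the elongation factor EEF1G (0.67 ± 0.16) and the RNA helicases EIF4A1 (0.42 ± 0.11) and EIF4A2 (0.59 ± 0.16). The list's median was 0.15 (camera adjusted p = 0.000327; adjusted p = 0.497 with an estimated correlation). Of 25 extracellular matrix genes 4 fell (6 when adjusted over the list alone), among them LAMB1 (-0.96 ± 0.14) on chromosome 7, LAMA5 (-0.49 ± 0.12) and the urokinase PLAU (-0.44 ± 0.11). That list's median was -0.12 (camera adjusted p = 0.000475; adjusted p = 0.512 with an estimated correlation), and it did not pass without control replicate 2 (adjusted p = 0.131). Of 20 heat shock genes 2 rose (CCT4, 0.46 ± 0.11, and DNAJA1, 0.49 ± 0.13) and 2 fell (HSPB1, -0.56 ± 0.14, on chromosome 7, and BAG3, -0.49 ± 0.13), or 5 and 2 when adjusted over the list alone. Their median was 0.15 (camera adjusted p = 0.0383; adjusted p = 0.512 with an estimated correlation), and the list did not pass without control replicate 2 (0.533) or double modulation replicate 2 (0.544). The other 19 tested lists did not pass. Of the 50 ribosomal protein genes, RPS3 (0.46 ± 0.11) and RPS4X (0.42 ± 0.11) rose and RPL19 fell (-0.63 ± 0.14), and the list had a median of 0.00 and 7 risen and 5 fallen when adjusted over the list alone. The replication genes MCM7 on chromosome 7 (-0.59 ± 0.11) and RFC4 (0.72 ± 0.19) went in opposite directions among 25, with a median of 0.02. PDIA4 on chromosome 7 (-0.47 ± 0.12) was the 1 of 20 unfolded protein response genes that fell, with a median of -0.09. Of 8 luminal markers CLDN4 fell (-0.96 ± 0.19) and CLDN7 rose (1.02 ± 0.29), with a median of 0.16. No member passed over all genes in the lists of aminoacyl-tRNA synthetases (22 genes, median 0.12), integrated stress (17, 0.09), tRNA processing and polymerase III (26, 0.06), the proteasome (29, 0.08), splicing factors (29, 0.07), mitochondrial ribosome (28, 0.06), nuclear-encoded oxidative phosphorylation (30, 0.01) and mitosis (25, 0.13). The same held for glycolysis (19, 0.00), hypoxia (14, 0.08), immediate early genes (17, 0.07), interferon response (19, -0.09), NF-kB targets (10, -0.11), p53 targets (13, 0.03) and YAP targets (15, -0.07). When adjusted over the list alone, 1 synthetase gene rose and 1 fell, 1 integrated stress gene fell, and the rest of these lists had 0 by edgeR.

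Overexpression of tRNA-Ile-UAU alone raised the footprints of GBP2 and RPL7A and lowered those of 0 genes, of 8143 tested by edgeR's quasi-likelihood test. An unadjusted p under 0.05 was reached by 409 (5.02%), about the 0.05 share that chance alone would give. GBP2, an interferon-induced GTPase on chromosome 1 (89106132 to 89126114), rose 2.40-fold, from 35.5 ± 6.99 to 84.6 ± 6.40 CPM (SD, n = 2; log2 1.26 ± 0.28, adjusted p = 0.0423). Its total RNA stayed at 47.6 ± 10.2 and 51.5 ± 2.78 CPM. RPL7A, a protein of the large ribosomal subunit encoded on chromosome 9 (133348218 to 133351426), rose 1.78-fold, from 124 ± 1.81 to 215 ± 57.1 CPM (log2 0.83 ± 0.18, adjusted p = 0.0423). Among the genes with lower values, INSIG1 (-0.69 ± 0.18, adjusted p = 0.282), the endocytic adaptor EPS15 (-1.19 ± 0.32, adjusted p = 0.346) and the fatty acid desaturase FADS2 (-0.42 ± 0.12, adjusted p = 0.454) had the lowest p and did not pass. The count was 0 and 0 without control replicates 1 and 2, 3 without replicate 1 of the construct group (the shallowest library, and the one farthest from its partner on the leading principal component of the footprints) and 1 without its replicate 2. It was 0 by DESeq2 (82 with an unadjusted p under 0.05), 0 by limma-voom with sample weights (461), 0 with no filter on low counts, 0 with the footprint libraries thinned to the shallowest, 4 with a replicate block and 8 with only the groups compared. GBP2 kept its call in 0 of the 4 leave-one-out fits and RPL7A in 1, without replicate 1 of the construct group.

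In the same comparison the footprints of 21 cholesterol genes had a median of -0.26 with 18 lower (camera adjusted p = 1.13e-05; adjusted p = 0.559 with an estimated correlation). Those of 16 histone genes had one of -0.20 with 14 lower (0.000105; adjusted p = 0.559 with an estimated correlation). Footprints were higher for 19 interferon response genes (median 0.32, camera adjusted p = 0.0286; adjusted p = 0.559 with an estimated correlation), 8 luminal markers (0.22, 0.0462; adjusted p = 0.559 with an estimated correlation) and 29 translation factors (0.09, 0.0464; adjusted p = 0.939 with an estimated correlation). In these lists 0 members passed over all genes by edgeR, and 1 cholesterol gene, INSIG1, fell when adjusted over the list alone. IFI44 (0.73 ± 0.30) and OAS2 (0.72 ± 0.38) had the lowest p among the interferon genes, and KRT18 (0.25 ± 0.14) among the luminal markers. The histone list did not pass without control replicate 2 (adjusted p = 0.0663) or construct replicate 2 (0.272). The interferon list did not pass without control replicates 1 (0.0641) and 2 (0.188) or construct replicate 2 (0.878), nor the translation factors without control replicate 2 (0.521) or construct replicate 2 (0.814). The luminal list did not pass without any of the 4 libraries (control replicates 0.421 and 0.0663, construct replicates 0.102 and 0.277), and it and the translation factors did not pass without chromosome 7 genes (0.0667 and 0.0628) or with the footprint libraries thinned to the shallowest (0.0563 and 0.0563).

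The interaction asks whether the construct acts differently in the 2 CRISPRi backgrounds. It passed for ROR2, LSM4, CD55, PDGFC and TGM2, all with a more negative effect of the construct in knockdown cells. In the other direction it passed for 0 genes. Of the 8143 tested, 475 (5.83%) had an unadjusted p under 0.05, near the 0.05 share that chance would give. ROR2 footprints were 54.9 ± 17.7 CPM in control, 64.3 ± 2.02 with the construct, 67.6 ± 42.8 with the knockdown and 13.9 ± 7.50 with both (interaction log2 -2.59 ± 0.45, adjusted p = 0.000356). The complement regulator CD55 went from 352 ± 2.94 to 443 ± 77.2 CPM with the construct in control cells and from 526 ± 88.5 to 368 ± 10.3 in knockdown cells (-0.87 ± 0.18, adjusted p = 0.0132). LSM4, a subunit of the U6 snRNA-binding Lsm ring, had an interaction of -0.80 ± 0.15 (adjusted p = 0.0023). Its footprints were 2666 ± 386 CPM in control, 3469.9 ± 226 with the construct, 3783 ± 620.0 with the knockdown and 2840.5 ± 1036 with both, against 52.4 ± 2.94 CPM of total RNA in control. The growth factor gene PDGFC had an interaction of -1.44 ± 0.33 and the transglutaminase gene TGM2 of -0.72 ± 0.17 (both adjusted p = 0.0447). In the knockdown alone LSM4 (0.51 ± 0.11), CD55 (0.58 ± 0.13), PDGFC (1.09 ± 0.23) and TGM2 (0.72 ± 0.12) had risen. EEF1G (0.97 ± 0.24, adjusted p = 0.067), CKS2 (1.15 ± 0.29, adjusted p = 0.0989) and SNX6 (0.97 ± 0.26, adjusted p = 0.183) had the lowest p among the positive interactions and did not pass. The 50 ribosomal protein genes had a positive interaction in footprints (median 0.21, 39 of 50, camera adjusted p = 1.71e-05; adjusted p = 0.689 with an estimated correlation). In that list 0 members passed over all genes by edgeR and 1 when adjusted over the list alone. RPS16 (0.64 ± 0.18) had the lowest p. The count of 5 was 0 by DESeq2 (76 with an unadjusted p under 0.05) and 0 with both assays in 1 fit (323), and 8 with a replicate block. It was 2 with the footprint libraries thinned to the shallowest, where LSM4 alone of the 5 passed. It was 1 and 1 without control replicates 1 and 2, 4 and 0 without construct replicates 1 and 2, 3 and 10 without knockdown replicates 1 and 2, and 6 and 9 without double modulation replicates 1 and 2. The 5 genes all lost the call without construct replicate 2 (highest adjusted p = 0.932). Of them, 4 lost it without control replicate 1 (0.399), 4 without control replicate 2 (0.260) and 3 without knockdown replicate 1 (0.627). The call was lost for 2 without double modulation replicate 1 (0.218), for 2 without construct replicate 1 (0.202), for ROR2 without knockdown replicate 2 (0.209) and for PDGFC without double modulation replicate 2 (0.0644).

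In total RNA the double modulation raised CDH11 and ZNF10 and lowered 6 genes, among them LAMB1, SEMA3C, SLC35B4, CYP51A1 and HTR1F, of 11720 tested. CDH11 rose from 16.5 ± 0.329 to 67.5 ± 5.03 CPM (log2 2.03 ± 0.16, adjusted p = 0.0024) and ZNF10 from 108 ± 3.93 to 233 ± 40.9 CPM (1.11 ± 0.13, adjusted p = 0.0266). LAMB1 fell from 351 ± 6.48 to 187 ± 5.42 CPM (-0.91 ± 0.11, adjusted p = 0.0266). The semaphorin SEMA3C (log2 -0.87 ± 0.10, adjusted p = 0.0255), the nucleotide sugar transporter SLC35B4 (-0.87 ± 0.11, adjusted p = 0.0384) and CYP51A1, lanosterol demethylase (-0.78 ± 0.11, adjusted p = 0.0493), fell too. These 4 genes lie on chromosome 7, whose 553 tested genes had a median of -0.35. The serotonin receptor gene HTR1F, outside the rule for named genes and chosen after its values were seen, stood at 12.5 ± 0.737 CPM in control and 0.348 ± 0.240 with both changes (adjusted p = 0.0255). The knockdown alone raised CDH11 (2.34 ± 0.16, adjusted p = 0.000688) and ZNF10 (1.29 ± 0.13, adjusted p = 0.0182) and lowered LAMB1 (-0.92 ± 0.11, adjusted p = 0.0445). The construct alone changed 0 genes by edgeR (233 with an unadjusted p under 0.05), 1 by DESeq2 and 1 by limma-voom with sample weights. The interaction changed 0 by edgeR (312 with an unadjusted p under 0.05), 0 by DESeq2 (89) and 0 by limma-voom with sample weights (324). The 233 and 312 by edgeR are 1.99% and 2.66% of the tested genes, under the 0.05 share that chance would give. Replicates 1 and 2 of the double modulation differed far more than the other pairs of both assays (13.9 chi-square per degree of freedom against 1.12 to 2.29). The 8 genes of the double modulation were 0 and 0 without control replicates 1 and 2, 293 and 1854 without double modulation replicates 1 and 2. They were 54 by DESeq2, 3 by limma-voom with sample weights, 0 with only the groups compared and 1 with a replicate block. They were 4 without chromosome 7 genes, 185 with no filter on low counts and 507 with the ribosomal protein score of each library as a covariate. The 3 genes of the knockdown were 0 and 0 without control replicates 1 and 2, 1 and 1 without knockdown replicates 1 and 2. They were 41 by DESeq2, 178 by limma-voom with sample weights, 236 with only the groups compared, 99 with no filter and 410 with the score. The 0 of the construct were 4 with only the groups compared, 5 with no filter and 15 with the score. The interaction's 0 were 2 and 520 without double modulation replicates 1 and 2, 40 with no filter and 35 with the score.

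Ribosomal protein mRNAs set the RNA libraries of the double modulation apart from each other. Their mean log2 CPM over that of all tested genes was 3.08 in replicate 1 and 2.10 in replicate 2, against 1.94 to 2.52 in the other 6 RNA libraries, and the median gene of the list was 2.04-fold higher in replicate 1. In the footprint libraries of that group the scores were 2.09 and 2.07. In total RNA all 54 ribosomal protein genes were higher in the double modulation (median 0.37, camera adjusted p = 6.46e-07; adjusted p = 0.737 with an estimated correlation). But 0 of them passed by edgeR over all genes or when adjusted over the list alone, and the median was -0.24 without double modulation replicate 1. With the construct alone their median was -0.24, with 50 of 54 lower (2.23e-09; adjusted p = 0.665 with an estimated correlation). In the interaction it was 0.58 (2.6e-12; adjusted p = 0.523 with an estimated correlation), against -0.07 (adjusted p = 0.216) without double modulation replicate 1.

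**Figure D3:**
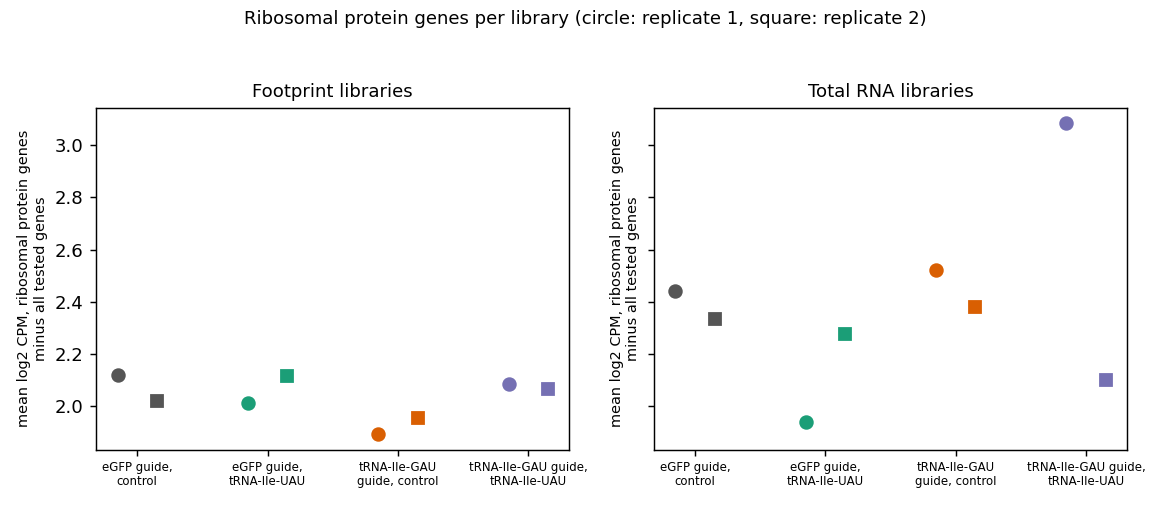
Mean log2 CPM of the ribosomal protein genes minus that of all tested genes, 1 point per library (circle for replicate 1, square for replicate 2), for footprints on the left and total RNA on the right. In total RNA, replicate 1 of the double modulation stands at 3.08 and replicate 2 at 2.10.

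Other lists passed in total RNA, where CYP51A1 was the 1 member of any of them to pass over all genes. Cholesterol synthesis genes had a median of -0.16 in the double modulation, where CYP51A1 was the 1 of 22 that fell and 3 fell when adjusted over the list alone (camera adjusted p = 2.25e-06; adjusted p = 0.606 with an estimated correlation; 0.253 without double modulation replicate 2). With the construct alone their median was -0.20 with 19 of 22 lower, 0 passing over all genes by edgeR and 1 when adjusted over the list alone (5.99e-08; adjusted p = 0.665 with an estimated correlation). The 13 tested histone genes had a median of -0.37 in the double modulation, with 1 risen and 1 fallen when adjusted over the list alone (0.0153; adjusted p = 0.606 with an estimated correlation), and the list did not pass without control replicate 1 (0.148) or without either double modulation replicate (0.125 and 0.108). In the knockdown alone 18 of 20 glycolysis genes were higher (median 0.20, adjusted p = 0.00144; adjusted p = 0.943 with an estimated correlation). The gene with the lowest p, the hexokinase HK2 (0.58 ± 0.14, adjusted p = 0.275), did not pass over all genes but rose when adjusted over the list alone. The glycolysis call was lost without control replicate 1 (0.0863) or knockdown replicate 1 (0.183). With the construct alone, mitochondrial ribosomal proteins were lower (median -0.11, 0.0452; adjusted p = 0.665 with an estimated correlation; lost without control replicate 1 at 0.438 or construct replicate 1 at 0.489). YAP targets were higher, with 1 risen when adjusted over the list alone (median 0.08, 0.0452; adjusted p = 0.665 with an estimated correlation). The YAP median was -0.05 without construct replicate 2, and the call was also lost without control replicate 1 (0.168). In the interaction mitochondrial ribosomal proteins had a median of 0.31 (0.0019), mitosis genes one of 0.14 (0.000511) and glycolysis genes one of -0.12 (0.0164), each with adjusted p = 0.523 with an estimated correlation. They were lost without double modulation replicate 1 (0.216, mitochondrial ribosome), without its replicate 2 (0.332, mitosis), and, for glycolysis, without control replicate 1 (0.271), construct replicate 1 (0.0714), knockdown replicate 1 (0.433) or double modulation replicate 2 (0.986).

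Most genes with changed footprints in the double modulation and the knockdown had total RNA on the same side, though for many of them the RNA did not reach an unadjusted p of 0.05. Across the 8012 genes tested in both assays, log2 fold changes of the double modulation correlated with r = 0.20 (Pearson, across genes, which are not independent). Of the 40 genes with risen footprints 39 had higher total RNA, with medians of 0.71 in footprints and 0.32 in RNA, and of the 110 with fallen footprints 93 had lower RNA, with medians of -0.67 and -0.31. The RNA had an unadjusted p under 0.05 on that side for 19 of the 40 and 45 of the 110, and the median changes of translational efficiency were 0.36 and -0.38. In the knockdown alone r was 0.27, and 30 of 35 risen and 45 of 52 fallen genes had RNA on the same side, 20 and 20 of them at an unadjusted p under 0.05, with median changes of translational efficiency of 0.17 and -0.33. The genes of these medians were chosen by their footprints, which also enter translational efficiency. Larger medians in footprints than in RNA, and the medians of efficiency, can therefore arise from that choice alone. For the construct alone r was 0.08 and 1 of the 2 risen genes had higher RNA, and for the interaction r was 0.12 and 2 of 4 genes had RNA on the same side. In total RNA of the double modulation S100A4 had a log2 fold change of -1.05 ± 0.46, PTK7 of 1.85 ± 0.32 and PON2 of -1.41 ± 0.28, without passing (adjusted p = 0.649, 0.112 and 0.143).

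**Figure D4:**
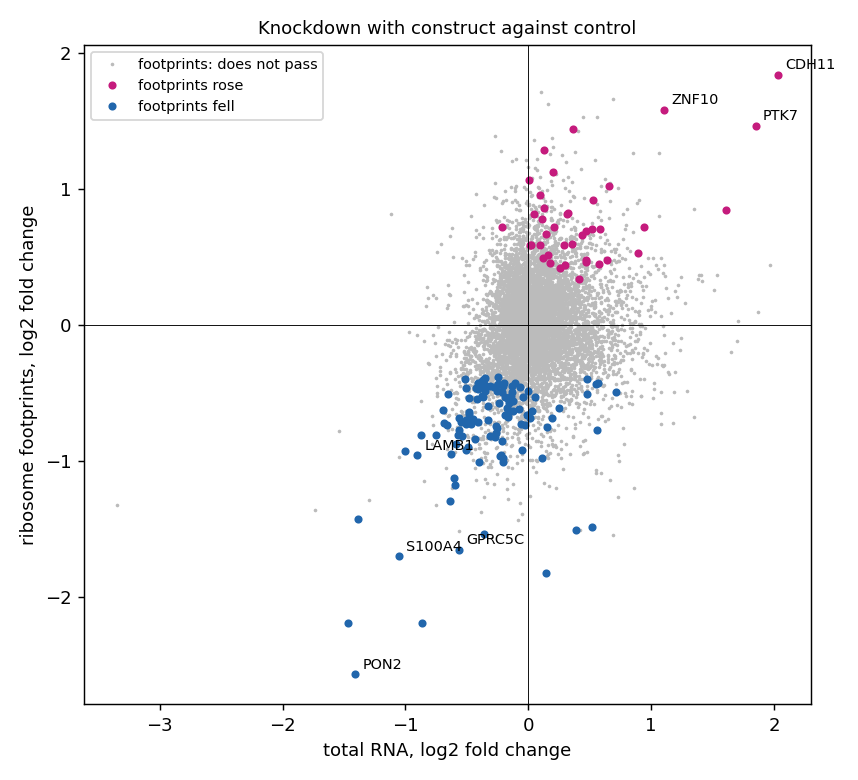
Log2 fold change of ribosome footprints (vertical axis) against that of total RNA (horizontal axis) for 8012 genes, double modulation against control, with genes whose footprints rose in magenta, those that fell in blue and the others in grey. CDH11, PTK7 and ZNF10 lie to the upper right and PON2 and S100A4 to the lower left; 39 of 40 risen genes lie right of 0.

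Translational efficiency, the change in footprints beyond that in total RNA, was tested as an interaction of assay and group over all 16 libraries. Of 8012 genes, 0 passed by edgeR in the double modulation, the construct alone, the knockdown alone or the interaction. An unadjusted p under 0.05 was reached by 335, 223, 268 and 201. These are 4.18, 2.78, 3.34 and 2.51%, under the 0.05 share that chance would give. DESeq2 (117, 70, 84 and 60 at an unadjusted p under 0.05) also called 0 in each comparison. So did limma-voom (218, 140, 172 and 147) and limma-voom with sample weights (317, 347, 426 and 217). The lowest p in the double modulation belonged to RFC4 (0.93 ± 0.22), ARPC1A (0.96 ± 0.24) and EXOSC3 (1.16 ± 0.34) among the higher genes and CCDC85C (-0.81 ± 0.20), MUL1 (-1.28 ± 0.33) and RPL19 (-0.66 ± 0.18) among the lower (all adjusted p = 0.940). S100A4 differed by -0.65 ± 0.54 and CDH11 by -0.18 ± 0.30. Genes of chromosome 7 had a median change of -0.06 in the double modulation and -0.01 in the knockdown alone. The double modulation's 0 became 15 and 620 without its RNA replicates 1 and 2 and 4 with the ribosomal protein score as a covariate; the interaction's became 84 without RNA replicate 2 and 7 with the score, and the construct's 2 with the score. In the lists that passed, 0 members passed by edgeR over all genes or when adjusted over the list alone. Ribosomal protein genes had lower efficiency in the double modulation (median -0.45, camera adjusted p = 0.00254; adjusted p = 0.868 with an estimated correlation). Their median was 0.36 without RNA replicate 1 of that group, and the adjusted p was 0.0711 without footprint control replicate 1. They were lower in the knockdown (-0.24, 0.00183; adjusted p = 0.907 with an estimated correlation; 0.0795 without footprint control replicate 1) and higher with the construct alone (0.22, 0.00142; adjusted p = 0.742 with an estimated correlation). The construct's call was lost without footprint control replicate 2 (0.166), footprint construct replicate 2 (0.318), RNA control replicate 1 (0.0615) or RNA construct replicate 1 (0.261). Extracellular matrix genes were lower in the double modulation (-0.25, 0.00649; adjusted p = 0.868 with an estimated correlation), a call lost without footprint control replicate 2 (0.230), footprint double modulation replicate 2 (0.322), RNA control replicate 1 (0.0967) or RNA double modulation replicate 1 (0.457). In the knockdown, extracellular matrix genes (-0.20) and glycolysis genes (-0.19) were lower (both 0.0111; adjusted p = 0.907 with an estimated correlation). Both of these calls were lost without footprint control replicate 1 (0.0546 and 0.0546), footprint control replicate 2 (0.188 and 0.0797), footprint knockdown replicate 2 (0.664 and 0.283), RNA control replicate 1 (0.134 and 0.144) or RNA knockdown replicate 1 (0.618 and 0.521).

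Each effect was also compared between the 2 backgrounds of the other, with comparisons that share no library. The footprint effects of the knockdown without and with the construct correlated with r = 0.25 across genes, and 24 genes were called in both. With the footprint libraries thinned to the shallowest, r was 0.18 and 9 were called in both, namely CDH11, ZNF10, S100A4, GPRC5C, CYR61, ITGB4 and, on chromosome 7, LAMB1, COPS6 and SND1. The count was 8 by DESeq2, 10 without chromosome 7 genes and 7 to 22 without 1 library. Of the 24, CDH11, ZNF10, PTK7, CTSC (cathepsin C), the laminin gene LAMB3 and TARS rose in both, 6 genes against 0.0727 by chance. Another 18 fell in both, against 0.371 by chance: 12 on chromosome 7, among them PON2, LAMB1 and IGFBP1, and S100A4, GPRC5C, CTGF, CYR61, LAMA5 and ITGB4 elsewhere; 0 genes were called in opposite directions. Without chromosome 7 genes r was 0.19. In total RNA r was 0.32 for the knockdown. For the construct without and with the knockdown r was 0.08 in footprints and -0.13 in total RNA, and 0 genes were called in both by edgeR, out of 2 and 36 in footprints and 0 and 0 in total RNA. For translational efficiency r was 0.19 for the knockdown and 0.00 for the construct.

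Markers of fibroblasts, immune cells and endothelium were mostly too low to test. Of 12 fibroblast markers 2 were tested in footprints and 4 in total RNA, of 12 immune markers 3 and 3, and of 9 endothelial markers 2 and 4, with 0 passing in any comparison by edgeR. The highest levels were those of CD74 (347 CPM in footprints, 28.3 in total RNA), ESAM (150 and 26.2 CPM) and TAGLN (16.8 CPM in footprints). Of the 16 long noncoding RNAs, all tested in total RNA and none in footprints, 0 passed by edgeR. MALAT1 was the highest at 8732 CPM. Of the 13804 genes listed for footprints, 12916 are protein coding by symbol, 22 are of another type and 866 have no type under their symbol. Noncoding genes may thus not have been counted there, and their absence is no measure of their footprints. Of the 13 mitochondrially encoded genes 0 matched a listed symbol, so they were not analysed here.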

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

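Of the tests in this part, those for sequencing depth, short mRNAs, base composition, a lost copy of chromosome 7, local repression, a translational effect and reads from a KRAB domain were chosen only after the result was seen; that for the region around ZNF10 was set before. The test of depth set before, thinning 1 library, was void because thinning keeps ratios, and was replaced. For short mRNAs and the KRAB domain, the bound that would have excluded the explanation was also rewritten after the value was seen, for the KRAB domain because it had treated ratios that the explanation does not forbid as excluding.

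A test of the difference itself, the interaction term, singled out results in which the effect of the construct differed between knockdown and eGFP cells by edgeR's test of genes or by camera with its preset correlation. In footprints these were ROR2 (-2.593), PDGFC (-1.44), CD55 (-0.8664), LSM4 (-0.8026) and TGM2 (-0.7216) and the median of the ribosomal protein list (0.2093; adjusted p = 0.689 with an estimated correlation). The 5 genes lost the call without construct replicate 2 (highest adjusted p = 0.932), and 1 to 4 of them without each of the other 7 footprint libraries (highest adjusted p 0.399 and 0.260 without control replicates 1 and 2, 0.202 without construct replicate 1, 0.627 and 0.209 without knockdown replicates 1 and 2, and 0.218 and 0.0644 without double modulation replicates 1 and 2). In total RNA they were the medians of the ribosomal proteins (0.5818), mitochondrial ribosome (0.3125), mitosis genes (0.1368) and glycolysis genes (-0.118), on the log2 scale; each had adjusted p = 0.523 with an estimated correlation. Both ribosomal calls were lost without double modulation replicate 1 (adjusted p = 0.216; cytosolic median -0.07) and the mitosis call without its replicate 2 (0.332). The glycolysis call was lost without control replicate 1 (0.271), construct replicate 1 (0.0714), knockdown replicate 1 (0.433) or double modulation replicate 2 (0.986).

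Ribosomal protein mRNAs differed between the total RNA libraries of the double modulation, 2.04-fold in the median gene. Both libraries belong to the same group, so no biological explanation was tested. Sequencing depth is argued against, since in the 4 other pairs of replicates whose totals differ at least as much, in footprints or total RNA, the fold of the deeper over the shallower library was at most 1.257. Base composition stays open: over 4696 genes outside the list, the median difference between these libraries was 0.4462 higher on GC-rich than on AT-rich chromosomes, so a shift with base composition in library preparation may be part of the difference. Better recovery of short mRNAs cannot be told apart, with a median difference of 0.08083 over 58 other genes of mostly short mRNAs and a bootstrap interval of -0.06 to 0.34.

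The median of chromosome 7 genes was lower with the tRNA-Ile-GAU guide than with the eGFP guide in footprints and total RNA, with and without the construct. Local repression at a single site of the guide is argued against, since the highest of the window medians was -0.2916 in the knockdown alone, and -0.25 over footprints and total RNA with the construct in both groups, and so is a translational effect, since the median change in translational efficiency was -0.005265 over 367 genes. A copy number of chromosome 7 that differs between the arms, such as loss of a copy with the tRNA-Ile-GAU guide, is a candidate explanation. All 8 windows had medians under -0.2 in footprints and total RNA, with and without the construct. These medians only compare the arms, so they cannot tell in which arm copies would have changed. Going from 4 copies to 3 would give -0.42, but no DNA data were used here and the copy number of these cells is not known from the files. Whether such a difference would come from the guide, the tRNA or the cells that received it stays open and untested, because these coincide in the design.

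ZNF10 counts were higher with the tRNA-Ile-GAU guide, and its KRAB domain is the one many CRISPRi repressors carry. A change of the whole region is argued against, since the median of the 12 other tested genes within 1 Mb was 0.008554. Whether the reads come from the endogenous gene or from a repressor with this domain cannot be told apart, because the files hold counts per gene and not positions within it. In the control libraries ZNF10 footprints stood at 0.7564 of the level of ZNF207, the highest of the other genes with a ZNF symbol. ZNF10 ranked 3 among the 114 tested genes with such a symbol, at 8.04 times their median. These levels leave room for either source. If the repressor is the source, ZNF10 may report its level in each arm.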

How the results depend on the processing

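Limma-voom with sample quality weights, the ribosomal protein score as a covariate, lists without each library in turn, fits without chromosome 7 genes and thinned footprint libraries were chosen after the data were seen; the other alternatives were planned. With 2 libraries per group, 1 library decides many calls; where it is left out, the lone library is assumed to vary like the other groups. Small changes were mostly missed at these depths and spreads. The tests called 26.5% of simulated 1.5-fold changes in footprints, 4% in total RNA and 1.02% in translational efficiency (TE). Depth alone does not set these shares, since total RNA was the deeper assay. Its biological coefficient of variation was larger (14.3% against 6.71% in footprints). That spread is shared by all RNA groups and includes the double modulation, whose replicates differed by 13.9 chi-square per degree of freedom. The other RNA groups had 1.33 to 2.29, so the low shares need not hold for total RNA in general. Planned tests of isoleucine codon lists, codon scores per library and codon ranking, with their alternatives on codon measure, list size, base composition and permutation, were not run for want of coding sequences. Where a value below moved, the cause was not tested, except that fits without chromosome 7, with fewer genes, lose the genes of that chromosome by construction.

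Size factors in place of TMM moved medians by at most 0.004 on the log2 scale and left the counts of genes and lists within 1.5 times. Over the alternatives and libraries left out, the 37 named results in footprints kept their call in 285 of 426 values, lost it in 141 and reversed in 0. DESeq2 gave no adjusted p for 18 of 20 named genes of the double modulation and 8 of 10 of the knockdown in footprints, nor for 3 of 8 of the double modulation in total RNA; these are not among the values, nor are 6 results whose genes fell under the filter after thinning. The 11 in total RNA kept it in 77 of 124, lost it in 47 and reversed in 0. Lists kept their call in 87 of 108 values in footprints, 80 of 100 in total RNA and 45 of 66 in TE, lost it in 21, 17 and 20 and reversed in 0, 3 and 1.

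By DESeq2, footprint counts were 48 in the double modulation, 0 for the construct, 25 for the knockdown, 8 for the knockdown in both backgrounds and 0 for the interaction, and total RNA counts 54, 1 and 41 in the double modulation, the construct and the knockdown. With no filter on low counts, the construct called 0 in footprints and total RNA called 185 in the double modulation, 5 for the construct, 99 for the knockdown and 40 for the interaction. With only the groups compared, the construct called 8 in footprints, and total RNA 0, 4 and 236 in the double modulation, the construct and the knockdown. With both assays in 1 fit the footprint interaction called 0. Limma-voom with sample quality weights called 0 for the construct in footprints, and 3, 1 and 178 in total RNA in the double modulation, the construct and the knockdown.

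With the ribosomal protein score as covariate, total RNA counts were 507 in the double modulation, 15 for the construct, 410 for the knockdown and 35 for the interaction, and TE counts 4 in the double modulation, 2 for the construct and 7 for the interaction. With genes of chromosome 7 left out, footprint counts were 98 in the double modulation, 42 in the knockdown and 10 for the knockdown in both backgrounds, the total RNA count in the double modulation was 4, footprint lists of the construct were 3, total RNA lists of the knockdown 2, and the agreement between backgrounds in footprints 0.19 for the knockdown. Over genes above the median mean count, agreement for the knockdown was 0.36 in footprints and 0.42 in total RNA. With an estimated inter-gene correlation, 0 fixed gene lists passed in footprints or total RNA in the double modulation, the construct, the knockdown or the interaction, and 0 in TE in the double modulation, the construct or the knockdown.

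With the footprint libraries thinned to the 358340 counts of the shallowest, footprint counts were 82 in the double modulation, 0 for the construct, 59 for the knockdown, 2 for the interaction and 9 for the knockdown in both backgrounds, and agreement between backgrounds in footprints was 0.18 for the knockdown and 0.0501 for the construct.

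The labels do not pair samples by replicate number, and the values gave no pairing that holds across groups. With a replicate block, the footprint counts were 4 for the construct and 8 for the interaction, the total RNA count in the double modulation was 1, and total RNA lists of the construct were 2. The block changed these and left the other counts within 1.5 times; TE called 0 genes with it and with a block by culture.

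Leaving out 1 library, footprint counts ranged from 35 to 133 in the double modulation, 0 to 3 for the construct, 18 to 46 for the knockdown, 0 to 10 for the interaction and 7 to 22 for the knockdown in both backgrounds. In the double modulation, the construct, the knockdown and the interaction, total RNA counts ranged from 0 to 1854, 0 to 0, 0 to 1 and 0 to 520, and TE counts from 0 to 620, 0 to 0, 0 to 0 and 0 to 84. Passing lists in that order ranged from 3 to 8, 1 to 5, 1 to 3 and 1 to 5 in footprints, 2 to 7, 2 to 5, 0 to 3 and 3 to 7 in total RNA, and 1 to 4, 0 to 3, 0 to 4 and 0 to 4 in TE. Some list medians reversed without 1 total RNA library. Over the libraries left out, the ribosomal protein median ranged from -0.24 (without double modulation replicate 1) to 0.80 (without its replicate 2) in total RNA of the double modulation, from -0.0722 to 1.05 in the interaction and from -0.88 (without its replicate 2) to 0.36 (without its replicate 1) in TE. The YAP median of the construct in total RNA ranged from -0.0505 (without construct replicate 2) to 0.27 (without its replicate 1).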

Other observations

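All tests in this part were chosen only after the result was seen.

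Off chromosome 7, the footprints of the 4 libraries with the tRNA-Ile-GAU guide and the 4 with the eGFP guide differed in 91 genes, and 1 of the 35 splits of the 8 libraries into 4 and 4, the real split itself, called as many; the highest of the others called 7. With the libraries thinned to the shallowest, since depth differs between these arms, the real split called 47 and the highest other 4. These counts cannot decide whether chance in how the 8 libraries divide gave the difference. Every other split mixes the CRISPRi arms on each side, so the arm difference enters its spread and can lower its calls. The guide comparisons had already called genes when the test was chosen, 1 of 35 is the smallest share possible, and replicates may be technical. Nor do the counts say what parted the arms. The split by construct called 7 genes off chromosome 7, and 2 of the 35 splits called as many, itself and the split by CRISPRi target with 91, so chance cannot be excluded by this count. That other split calls several times the count of the construct, which points to a structure of the samples, namely the CRISPRi arms. The other 33 splits called at most 2. In total RNA the split by CRISPRi target called 214 genes, 93 of them off chromosome 7, and the highest other split called 0 off it; the split by construct called 0 genes by edgeR, with 210 at an unadjusted p under 0.05.

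With chromosome 7 included, the split by construct called 9 genes in footprints. PPAT (1.04), EEF1G (0.77), RPL7A (0.70), RPS18 (0.64) and VSTM2A (1.51, on chromosome 7) were higher with the construct, and HIST1H2BF (-1.49), INSIG1 (-0.74, on chromosome 7), FADS2 (-0.45) and the fatty acid synthase FASN (-0.47) lower, as log2 fold changes with adjusted p from 0.00851 to 0.0379.

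Scores per library of the fixed lists, compared between 4 and 4 footprint libraries by exact permutation, reached the smallest p that 70 arrangements allow (0.0286) for cholesterol synthesis and histones (lower with the construct), luminal markers and translation factors (higher with the construct) and extracellular matrix (lower with the tRNA-Ile-GAU guide). In total RNA the cholesterol list, lower with the construct, reached it too. After adjustment over 98 tests the value was 0.467 for each. The smallest p could pass this adjustment only if most of the 98 tests reached it, so the adjusted values cannot decide.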
